A study of Schizosaccharomyces pombe with 25 samples.

How the data were processed

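The series comprises 25 chromatin immunoprecipitation sequencing libraries of Schizosaccharomyces pombe. Per the labels' protocols, overnight cultures were fixed with formaldehyde and sheared by sonication, CENP-A was precipitated with anti-Cnp1 serum and the tagged proteins with anti-Myc or anti-Flag antibody, and Illumina libraries were amplified by PCR. The submitters' processing notes name BWA, Bowtie2, SAMtools, deepTools 2.5.3 and bedtools, and the genome build ASM294v2. Their settings, and the role of each tool, are not given in the sources used here. Samples were grouped by the precipitated protein, strain and genotype in the labels, which gave 13 groups. No value of a sample was analysed here, so no enrichment, replicate spread or depth is reported, and the comparisons between genotypes were not made.

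The 3 files used belong to the series as a whole and describe the reference genome of the strain with the exchanged central core. The first is a gene annotation with 32869 rows, of which 0 carry a score. The second, deposited as a list of regions, holds the names of the 7 sequences and no region. The third lists for each of 7 sequences its offset, its length and its number of ambiguous stretches, in the layout that the BWA indexer writes. These values are positions and lengths in bases as the authors deposited them, with no normalisation. How the authors built the modified chromosome is not given in the sources used here.

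For comparison, the RefSeq sequence and annotation of assembly ASM294v3 were used, which is not the build the labels name. Chromosomes I and III had the same length and the same number of ambiguous stretches (1 and 3) in both, and chromosome II the same number of ambiguous stretches (2). The mitochondrial sequences differed in length (19431 and 19433 bases), so no mitochondrial coordinate was carried over. Whether nuclear coordinates mean the same place in both was checked by reading all annotated start codons of 3 unsplit bases on the comparison sequence. Coordinates on IIc are those of the deposited annotation, and coordinates called unmodified are those of chromosome II in the comparison assembly. Genes were paired by systematic identifier, ignoring letter case, and 6841 of 6968 nuclear genes (98.2%) found a partner on the same chromosome. The strand differed for 6 of them. An earlier pairing through database cross-references had missed the tRNA genes and was replaced.

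A centromeric interval was defined, before the data were examined, as the longest interval between adjacent protein-coding genes of each nuclear chromosome. tRNA genes overlapping the intervals were counted and compared with 100000 random placements of intervals of the same length on the same chromosomes, in a 1-sided permutation test, with Benjamini-Hochberg adjustment over the chromosomes tested alone. The threshold was 0.05. Genes within 20 kb of an interval were listed by distance and strand. The central domain was defined only after the data were examined, as the stretch between the closest pair of tRNA genes for the same amino acid on opposite strands of an interval. GC content was compared with windows of the same length at steps of 500 bases. A position was called unique if its 50-base sequence occurred once in the comparison genome, counting both strands, and a share of positions leaves out sequences with ambiguous bases. The 95% intervals are Wilson intervals.

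The genes named in the text were fixed before the data were examined. They are 5 lists (the factors of the labels, the Swr1 complex, CENP-A assembly and the kinetochore, heterochromatin and histones), the first 5 protein-coding genes on each side of each interval, the tRNA genes nearest to the centre of an interval, and the genes missing from or added to chromosome II, of which the larger sets are given as counts. The bounding genes of the gap in which positions change and of the central domains, and sme2, were named after their values were seen. eic1 was found through the symbols of the RefSeq gene table, and the other listed genes by their name in the deposited annotation. Alternatives changed which tRNA genes count, the width of the interval and of the flanks, the random placement, the matching of genes, the GC window and the sequence length of 50 bases.

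The permutation test was tested on simulated data, with 171 tRNA genes placed at random in 200 simulations. It passed the threshold in 3.5% of them with no gene planted in the intervals, in 36.0% with 1 gene planted per interval and in 100.0% with 5 per interval. The simulated genes were placed independently of each other, with fewer random placements per test. These rates need not hold for tRNA genes that lie in groups. The search for unique sequence found 7804 of 7804 positions made non-unique in a simulated sequence of 64000 bases. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.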

Results

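The series asked how the histone variant H2A.Z, called Pht1 in the fission yeast Schizosaccharomyces pombe, and the Swr1 chromatin remodeller that deposits it relate to the assembly of CENP-A on centromere DNA. CENP-A, called Cnp1 in this yeast, is the histone H3 variant that marks active centromeres. The labels listed 25 chromatin immunoprecipitation sequencing samples in 13 groups. CENP-A was precipitated in 9 samples. Of these, 4 came from strains labelled cc2∆:cc1, in which the central core of centromere II (cc2) was deleted and that of centromere I (cc1) stood in its place, with 1 sample each for wild type, pht1∆, swr1∆ and msc1∆. The other 5 CENP-A samples came from strains with no such exchange in their labels, with 2 wild-type samples and 1 sample for each of the same deletions. H2A.Z(Pht1) was precipitated in 12 samples, 4 each from wild type, swr1∆ and msc1∆. Swr1 and Msc1, a protein of the Swr1 complex, were each precipitated in 2 wild-type samples. The comparisons of CENP-A and H2A.Z between genotypes were not analysed here, because the 3 files used describe the modified reference genome and hold no value of any sample. Sequencing depth per sample is likewise unknown here. What follows describes where gene positions change on the modified chromosome II of that reference, and which genes surround the centromeres. The GC content, and how much of each centromere has a sequence that occurs once, were computed on the unmodified comparison genome instead.

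The modified reference held 12649822 bases in 7 sequences. Chromosomes I and III were 5579133 and 2452883 bases long, the same lengths as in the reference assembly used for comparison. The modified chromosome II, named IIc, was 4538954 bases long, against 4539804 for the unmodified chromosome, a difference of 850 bases. The other sequences were the mitochondrial genome (19431 bases), 2 named MTR (20128 bases) and AB325691 (20000 bases), and pHetcc2 (19293 bases), which carried no annotated gene. The annotation listed 7015 genes. There were 5143 protein-coding genes, 1536 non-coding RNA genes, 196 tRNA genes, 49 rRNA genes, 55 small nucleolar RNA genes, 7 small nuclear RNA genes and 29 pseudogenes. Chromosome I carried 3127 of them, IIc 2552 and III 1289.

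Gene positions on the modified chromosome II changed at 1 place, in the centromere, and by 1 distance among the genes of equal length. Genes of equal length kept their unmodified position up to the non-coding RNA gene SPNCRNA.368 (1619808 to 1620391). Genes of equal length from the valine tRNA gene SPBTRNAVAL.07 onward (1628309 to 1628391 on IIc, 1629159 to 1629241 on the unmodified chromosome II) stood 850 bases further left, and 0 genes of equal length were on the wrong side of this gap. The net change in length therefore fell within 7917 bases of IIc, from 1620392 to 1628308, a gap that measures 8767 bases on the unmodified chromosome, from 1620392 to 1629158. The ends of the exchanged segment were not determined, since a replacement of equal length beyond the gap would leave these positions as they are. The 2 non-coding RNA genes annotated in that gap on the unmodified chromosome, SPNCRNA.369 (1620799 to 1620937) and SPNCRNA.370 (1625750 to 1626227), were missing from the annotation of IIc, and 0 genes were annotated in the gap on IIc.

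Of the 2552 genes of IIc, 2502 shared an identifier with a gene of chromosome II in the comparison annotation. Among these, 279 had the same length and position, 423 had the same length and stood 850 bases to the left, and 1800 differed in length. Comparison by identifier alone, with either end of the gene at the expected place, gave 1592 moved and 890 unmoved genes, and 20 with both ends elsewhere. Comparison by the span from the first to the last coding base, which was chosen after seeing that transcript ends differed between the annotations, gave 1197 moved and 624 unmoved protein-coding genes, with 42 of another length, where the comparison of whole genes found 49 moved and 30 unmoved among the protein-coding genes. On chromosomes I and III, 0 genes had moved by that distance under any of these comparisons. The remaining 50 genes of IIc had no partner of the same identifier. They comprised 44 non-coding RNA genes, among them sme2, and 6 protein-coding genes. In all, 1636 of the 2552 genes of IIc (64.1%) and 1224 of its 1869 protein-coding genes (65.5%) lay to the right of the gap.

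**Figure D1:**
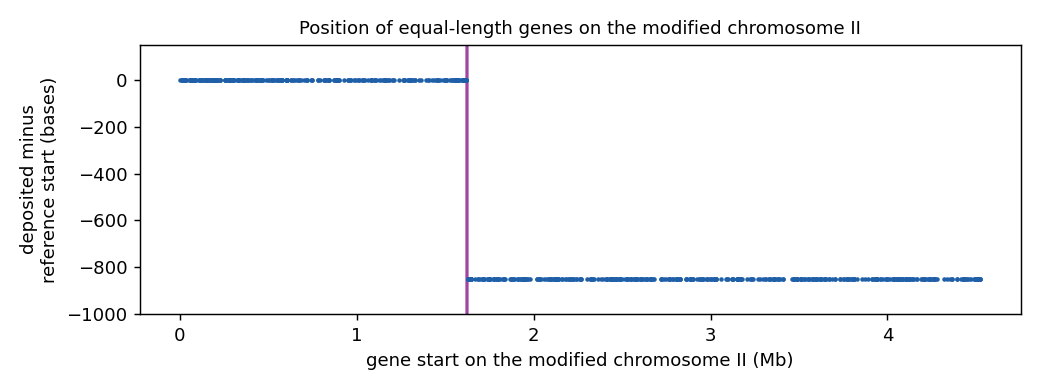
The start of each IIc gene that has the same identifier and length in the comparison annotation, in megabases on the modified chromosome, is plotted against the deposited minus the reference start, in bases. Points lie at 0 to the left of the purple band, which marks the gap from 1620392 to 1628308, and at -850 to its right.

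Start codons of the deposited annotation, read on the unmodified sequence, showed the same displacement. Read at the deposited coordinates on the unmodified genome, 2330 of 2330 annotated start codons of chromosome I and 919 of 919 of chromosome III were ATG (95% Wilson lower limits 99.8% and 99.6%). On IIc, the 644 start codons to the left of the gap were likewise all ATG. To its right, 26 of 1223 were ATG (2.13%, 95% Wilson interval 1.46% to 3.10%), and 1223 of 1223 were after moving each by 850 bases. The sequence of IIc was not read, and the 850 bases were taken from the same deposited positions. The start codons are therefore not separate evidence of the displacement.

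Each nuclear chromosome had one long stretch without protein-coding genes, taken here as its centromeric interval. On chromosome I it ran from 3751730 to 3790911 (39182 bases) between per1 and emc5. On IIc it ran from 1596745 to 1647302 (50558 bases) between rpb1, which encodes the largest subunit of RNA polymerase II, and yox1. On chromosome III it ran from 1064444 to 1142615 (78172 bases) between chk1, the DNA damage checkpoint kinase gene, and SPCC4B3.18. The next longest such stretches on chromosomes I, IIc and III were 6121, 12069 and 6772 bases. The intervals of chromosomes II and III held ambiguous bases on the unmodified genome, so their lengths need not be those of complete sequence.

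tRNA genes were concentrated in these intervals. That they border centromere cores in this species was known when the test was planned, so the test gives the size of an anticipated excess. The intervals covered 1.34% of the chromosomes and held 55 of the 171 nuclear tRNA genes (32.2%), of 15 amino acid kinds. Intervals of the same lengths placed at random held 2.70 ± 3.83 tRNA genes (mean ± SD of 100000 placements) and at most 45, so the observed number was 20.3 times the random mean (1-sided permutation test, p = 1e-05, the smallest value these placements can give). With the intervals widened by 20 kb on each side, the ratio was 12.3 (permutation p = 2e-05). With random intervals placed only in protein-coding-free DNA, a comparison added after seeing the data, the random mean was 13.9 ± 7.15 and the ratio 3.97 (permutation p = 1e-05). Away from the centromeric intervals no such stretch was as long, so these random intervals joined separate, shorter stretches. Per kb of protein-coding-free DNA there were 0.328 tRNA genes inside the intervals and 0.0512 outside them. The interval of IIc held 27 of that chromosome's 68 tRNA genes, against a random mean of 0.769 (permutation test, Benjamini-Hochberg adjusted p = 0.000765). Chromosome III had 21 of 47 in its interval, against 1.54 (adjusted permutation p = 0.000765), and chromosome I had 7 of 56, against 0.399 (adjusted permutation p = 0.0026). Random placements that covered the interval itself were kept, which raises the random means, lowers the ratios and sets a floor on the p of each single chromosome.

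The closest pair of tRNA genes for the same amino acid on opposite strands of each interval enclosed the stretch called the central domain here. Other such pairs lay further out, such as SPATRNAALA.04 and SPATRNAALA.05 on chromosome I. A domain bounded by an outer pair would be longer, and the arms shorter. On chromosome I, the isoleucine tRNA genes SPATRNAILE.03 (3768290 to 3768363, forward strand) and SPATRNAILE.04 (3773910 to 3773983, reverse strand) bounded 5546 bases. On IIc, the valine tRNA genes SPBTRNAVAL.06 (1619174 to 1619256, reverse strand) and SPBTRNAVAL.07 (forward strand) bounded 9052 bases, against 9902 bases between the same genes on the unmodified chromosome. On chromosome III, the leucine tRNA genes SPCTRNALEU.12 (1096085 to 1096185, reverse strand) and SPCTRNALEU.13 (1102809 to 1102909, forward strand) bounded 6623 bases. The domain of chromosome III also held a glutamate tRNA gene, SPCTRNAGLU.10, and that of chromosome I the non-coding RNA gene SPNCRNA.233. The domain of IIc retained SPNCRNA.367 and SPNCRNA.368 at its left edge. Across the 3 intervals there were 30 non-coding RNA genes, 9 on chromosome I, 14 on IIc and 7 on chromosome III.

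**Figure D2:**
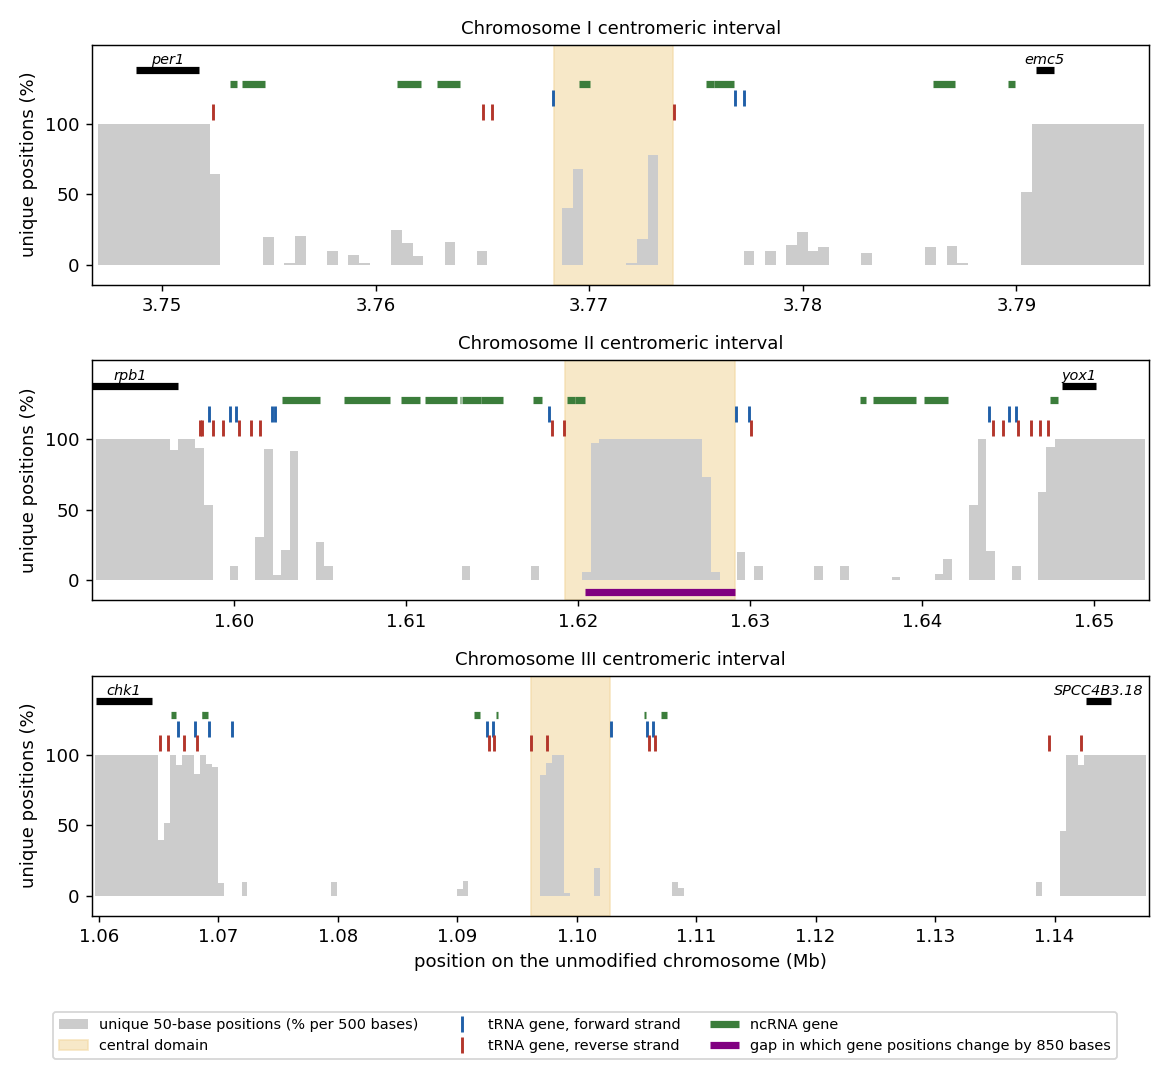
Maps of the 3 centromeric intervals by position on the unmodified chromosomes, in megabases, with tRNA genes by strand, non-coding RNA genes in green, the bordering protein-coding genes in black and, in grey, the percentage of positions per 500 bases whose 50-base sequence occurs once in the genome. Unique sequence fills most of the central domain of chromosome II (70.1%) and little of that of chromosome I (18.7%), and the purple bar marks the gap of 8767 bases between the last unmoved and the first moved gene.

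Within 20 kb of the 3 intervals there were 64 protein-coding genes, of which 36 were transcribed toward the interval and 28 away from it. The number was 32 within 10 kb and 140 within 50 kb. The first 5 genes to the left of the chromosome I interval were per1, rpl1002, prm1, lys1, which serves lysine synthesis, and gua2. To its right they were emc5, rad50, a DNA repair gene with its nearer end 841 bases from the interval, sdh1, which encodes a succinate dehydrogenase subunit, azr1 and cdd1. To the left of the IIc interval stood rpb1, SPBC28F2.11, ngg1, toa1 and SPBC28F2.08c. On its right, all within the part of the chromosome that had moved, stood yox1, rec6, a meiotic recombination gene, dpm2, the ribosomal protein gene rps402 and SPBC21B10.09. The chromosome III interval was bordered by chk1, meu27, ubc11, SPCC1259.12c and gyp2 on the left and by SPCC4B3.18, cmc2, cbp3, tip41 and mid1, a gene for placement of the division site, on the right.

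The central domains were poorer in G and C than their chromosomes. GC content was 28.2% in the domain of chromosome I, 28.1% in that of the unmodified chromosome II and 27.9% in that of chromosome III, against 36.1%, 35.9% and 36.2% over the whole chromosomes. The share of same-length windows with a GC content at or below that of the domain was 0.072% on chromosome I and 0.022% on chromosome II, and 0 of 4893 windows on chromosome III were as low. Windows that overlap the domain were kept, so low windows may lie on the domain itself. With 5 kb windows, compared with the 5 kb at the centre of each domain, these shares were 0.126% on chromosome I, 0.209% on chromosome II and 0.143% on chromosome III. The gap of 8767 bases on unmodified chromosome II in which positions change had a GC content of 28.2%. These are descriptions of single segments and were not tested.

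Most of each centromeric interval consisted of sequence that occurs more than once. On the unmodified genome, 8.88% of 50-base positions in the chromosome I interval, 24.6% in that of chromosome II and 11.5% in that of chromosome III had a sequence found once on either strand. The shares over the whole chromosomes were 96.8%, 96.3% and 93.1%. The central domain of chromosome II differed from the others in this respect, with 70.1% unique positions against 18.7% on chromosome I and 30.5% on chromosome III, and 79.2% in the gap in which positions change. These shares count every position of 1 genome sequence whose 50 bases are unambiguous, so no replicate error applies to them. Ambiguous bases lay inside the intervals of chromosomes II and III, and the sequence they stand for is not counted. They describe the genome without the exchange and without pHetcc2. The sequences of pHetcc2 and of the segment inserted into IIc were not used here.

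The genes of the 4 factors named in the labels lay outside the centromeric intervals. cnp1 (SPBC1105.17), which encodes CENP-A, lay on IIc from 3537331 to 3539313 on the forward strand, 1890 kb from the interval, and from 3538181 to 3540163 on the unmodified chromosome. pht1 (SPBC11B10.10c), which encodes H2A.Z, lay to the left of the gap on the reverse strand from 1502203 to 1503468, 93.3 kb from the interval. swr1 (SPAC11E3.01c, 5277395 to 5281420) and msc1 (SPAC343.11c, 1658316 to 1663346) were on the reverse strand of chromosome I, 1486.5 kb and 2088.4 kb from its interval. Each of the 4 genes was annotated with 1 exon.

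Of the 14 listed genes of the Swr1 complex, 6 were on chromosome I, 5 on IIc and 3 on chromosome III. swc3, on chromosome I, was the nearest to a centromeric interval, at 33.5 kb. Of these genes, 2 lay on the moved part of IIc, vps71 (2046055 to 2046933) and alp5 (2012138 to 2014155). Among 20 genes of CENP-A assembly and the kinetochore, 10 were on IIc, and 5 of these had moved, namely cnp1, cnp3, mis17, sim4 and fta3. The nearest of this list to an interval was mis15, at 146.6 kb. Among 11 heterochromatin genes, chp2 and stc1 had moved, and tas3, of the RNA-induced silencing machinery, was nearest to an interval, at 80.5 kb. Among 9 histone genes, the neighbouring hht3 and hhf3 had moved, while the other pair on IIc, hht2 and hhf2, had not. All members of the 5 lists were found in the annotation.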

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

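The comparison by coding span and the placement in protein-coding-free DNA were chosen after seeing the data, and the other alternatives before the data were examined. The excess of tRNA genes in the centromeric intervals kept its direction and its side of the threshold under the alternatives run: whole genes only, intervals widened by 10 or 20 kb, random intervals starting at gene ends or placed in protein-coding-free DNA, and each chromosome left out in turn. The ratio ranged from 3.97, in protein-coding-free DNA, to 29.1, without chromosome III, and the permutation p from 1e-05 to 2e-05. Leaving out the first and last 100 kb of each chromosome chose the same intervals and so moved nothing. The number of flanking protein-coding genes changed by construction with the width of the flank, to 32 at 10 kb and 140 at 50 kb. The number of moved genes on IIc rose from 423 to 1592 with genes compared by identifier alone, which does not require equal transcript ends. It was 1197 by coding span, which covers protein-coding genes alone, against 49 of the same set compared as whole genes. GC content in 5 kb windows at the centre of the domains and of the gap in which positions change stayed within the binomial interval of the whole segment. The share of windows with as low a GC content rose with 5 kb windows, to 0.126%, 0.209% and 0.143% for the domains of chromosomes I, II and III. The central 5 kb also had a higher GC content (28.4%, 28.5% and 28.4%) than the whole domains (28.2%, 28.1% and 27.9%). Its part in the rise and that of the shorter windows were not tested apart.

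The share of unique positions moved with the sequence length. With 36 bases it was 7.74%, 23.9% and 11.04% in the intervals of chromosomes I, II and III, and 17.6% in the central domain of chromosome I. With 100 bases it was 12.6%, 27.1% and 12.8% in the intervals, 22.1%, 72.0% and 33.2% in the central domains of chromosomes I, II and III, and 80.8% in the gap in which positions change. Longer sequences are unique more often by construction, and chromosome II had the highest share of the 3 chromosomes in both kinds of segment at each of the lengths run. No paired analysis was possible because the results come from features of an annotation and a genome sequence, which have no samples or replicates.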

Other observations

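The comparisons of repeat arms, of shared sequence between central domains and of missing identifiers were chosen after seeing the data. So was the test of copies of 1 tRNA gene. The test of protein-coding-free DNA was set before its result was seen.

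Most of the arm to the left of each central domain recurred in inverted orientation in the arm to its right. The share of the right arm found in the left was not computed. The left arms of chromosomes II and III held ambiguous bases, which these shares leave out. On chromosome I, 87.3% of the 50-base positions of the left arm had their reverse complement in the right arm, against 0.856% that recurred there in the same direction. The inverted share was 79.5% on chromosome III, with 0.108% in direct orientation. On chromosome II it was 64.6%, and the direct share was 17.7%. The central domains of chromosomes I and III held sequence in common, with 57.1% of the positions of the former found in the latter and 51.7% of the latter found in the former. The central domain of chromosome II shared 0 of its 9853 positions with either. Reads of 50 bases from these shared parts have more than 1 equally good place in the unmodified genome, before any further copy of the chromosome I core is added on chromosome II.

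The comparison annotation listed 5765 genes on chromosomes I, II and III with an identifier that the deposited annotation lacked, 2151 of them on chromosome II. Of the 5765, 5752 were non-coding RNA genes. Among non-coding RNA genes with an identifier number up to the highest in the deposited annotation, 3 of 1430 were missing. Of these, 2 were SPNCRNA.369 and SPNCRNA.370, both inside the gap on chromosome II in which positions change, and the other was SPNCRNA.817 on chromosome I.

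tRNA genes were dense in the centromeric intervals. The first technical account is that tRNA genes fill whatever room protein-coding genes leave. Intervals placed at random in the protein-coding-free DNA of the same chromosomes held 13.9 ± 7.15 tRNA genes (mean ± SD) and at most 53. They had to join separate stretches, since outside the centromeric intervals none was longer than 6121, 12069 and 6772 bases on chromosomes I, IIc and III. The observed number was 55 (1-sided permutation test, p = 1e-05, the smallest value possible), which argues against free room as the whole cause. The random mean was higher than the 2.70 of placement anywhere, and free room may account for part of the number. Placements that covered the intervals themselves were kept, however, and the tRNA genes of the intervals raise that mean. The second account, that the genes are all copies of 1 tRNA gene in the repeat arms, was set after the data were seen. Their 15 amino acid kinds contradict it in that narrow form, but say nothing of copied groups of different tRNA genes. Such groups did recur. On IIc, the tRNA genes from SPBTRNATYR.02 to SPBTRNAGLU.06 recurred from SPBTRNATYR.03 to SPBTRNAGLU.07, in the same order and on the same strands. On chromosome I, isoleucine, glutamate and alanine tRNA genes lay at equal distances on both sides of the domain's midpoint (2810, 5667 and 6092 bases). Some genes, such as SPATRNAPHE.02, had no such counterpart. Duplication of the arms may still account for part of the number. The 55 genes reduce to 28 distinct sequences when each is counted once per interval. Random intervals counted so, without the limit to protein-coding-free DNA, held 2.40 ± 2.70 and at most 27 (permutation p = 1e-05). Free room and duplication were therefore not tested together, and no biological explanation was tested.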
